A study of Sus scrofa with 6 samples.

How the data were processed

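Longissimus muscle of pigs (Sus scrofa) was profiled by RNA sequencing in 6 libraries, 3 from the group with high and 3 from the group with low intramuscular fat, the fat that lies between and within the bundles of muscle fibres. Per the labels' protocols, total RNA was extracted with TRIzol from freshly taken longissimus dorsi and made into Illumina TruSeq libraries, which were read on an Illumina HiSeq instrument. Per the submitters' processing notes, FastQC 0.10.1, Trimmomatic 0.22 and TopHat2 2.0.4 were used, and BWA 0.6.2 is named as well without a role. The read counter, its strand setting, the genome build and the annotation are not given in the sources used here. Coordinates are those of the deposited table. The last gene on chromosome 1 ended at 314.14 Mb in it and at 274.28 Mb in the RefSeq annotation of Sscrofa11.1, so the RefSeq table was used for names alone.

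The authors deposited a table of 7661 Ensembl genes with raw read counts per library, which are whole numbers. The deposited CPM (counts per 1e6 reads of the library total) of a library equalled the count divided by 1 whole-number library total for every gene, and those totals served as library sizes here. Every gene in the deposited table had a CPM above 10 in at least 3 libraries, so genes of lower abundance were not analysed here, and a gene found in 1 or 2 libraries alone could not enter the table. The authors' deposited log2 fold changes run from high to low (low over high) and were turned around here. The authors' p-values and false discovery rates stand beside them, per the file headers. A second deposited list holds 134 genes, which are those of the full table with a false discovery rate under 0.05 and an absolute log2 fold change of at least 1, and 1 line of it that names no gene was dropped. The authors' test is not named in the sources used here. edgeR's exact test with TMM factors and tagwise dispersions gave the same log2 fold changes to within 2.85e-08. Its log10 p-values were the same to within 1.05e-04.

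The comparison was high against low, with log2 fold changes as high minus low. The test was edgeR 4.0.16 (R 4.3.3) with TMM normalisation, filterByExpr, which kept all 7661 genes, and the quasi-likelihood F-test without covariates, with Benjamini-Hochberg adjustment and a threshold of 0.05. All adjusted p-values for genes come from that test unless another is named. Standard errors are the absolute log2 fold change divided by the square root of F. Expression levels are TMM-normalised CPM as mean ± SD over 3 libraries. The study design gives 3 pigs per group. Breed, sex, age and any pairing of the animals are not given in the sources used here. With 3 against 3 libraries an exact permutation test of a single value cannot go below p = 0.1. All tests allowed for a change in either direction.

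Gene lists (29) for lipid metabolism, muscle fibre type, energy metabolism and the other cell types of muscle were fixed before the data were examined. Of their 478 members, 162 were not matched by name to a further record. An unmatched member is not shown to be absent or low, since 716 records carried no symbol. Lists with at least 3 records were tested with camera of limma 3.58.1 on log2 CPM with a prior count of 2, a preset correlation of 0.01 and adjustment over the 24 lists tested; the same test with a correlation estimated per list was an alternative. Camera compares a list with the other genes of the table. Names came from the deposited table for 6381 genes, from an Ensembl name table for 428 (5336 IDs were found in it) and from RefSeq for 136, and 716 kept an Ensembl identifier. 198 symbols stood on more than 1 record, and such records can share reads.

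The rule for named genes was also fixed beforehand and, apart from the authors' list, left out genes without a symbol. It took the 10 genes per direction with the largest fold change among those past the threshold whose groups did not overlap, every list member past the threshold, up to 4 further members of each list past the list test by unadjusted p, 14 genes always named, in a direction with fewer than 5 called genes the next by unadjusted p up to 5, and the 5 genes per direction with the largest fold change in the authors' deposited list. ADIPOQ, LEP, FABP4, LPL and PPARG were among the 14 and are not analysed here.

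Alternatives planned before the data were examined were DESeq2 size factors or upper-quartile factors in edgeR, no filter, a mean CPM of at least 5, DESeq2 1.42.0 and limma-voom. The replicate number as a block, each library left out in turn, a threshold of 0.1 and, for the lists, ranks or an estimated correlation were planned as well. A change of pseudocount was planned for normalised values only and was not run. Alternatives added after seeing the data were edgeR's exact test, the older quasi-likelihood method, library sizes from the listed genes, removal of the 35 mitochondrially encoded genes, high libraries 1 and 2 left out together, and removal of the trend of log2 CPM with the genomic span of the genes in each library (medians of 50 bins of genes). Tables and figures were made with pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9.

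The steps were tested on simulated data with the means, dispersions and library sizes of these 6 libraries and 200 of 7661 genes changed. For high against low, the quasi-likelihood test recovered 61.2% of genes changed by a factor of 2 and 100% of those changed by a factor of 4, but 1.49% of those changed by a factor of 1.5, and 4.42% of its calls were false. The exact test recovered 83.6% at a factor of 2 with 17.0% false calls, DESeq2 83.6% with 18.1%, and limma-voom 55.2% with 3.70%. Of 1000 unchanged lists, camera called 1% at an unadjusted threshold of 0.05. These simulated genes varied independently, which real genes of a list do not. Removal of a simulated span trend took Spearman's rho from 0.552 to 0.0102.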

Results

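Transcript abundance was measured by RNA sequencing in longissimus muscle, the long back muscle, from 3 pigs with much and 3 pigs with little intramuscular fat (the high and low groups). Library totals were 25371989, 25503927 and 28874691 reads in high libraries 1 to 3 and 34813172, 31363850 and 30139025 reads in low libraries 1 to 3. The 7661 listed genes held between 96.6% and 97.2% of each total, and 3 counts corresponded to between 0.0862 and 0.118 CPM. Mitochondrially encoded genes took 7.08%, 6.99% and 11.5% of the high libraries and 12.7%, 8.96% and 8.06% of the low libraries. The first principal component, with 40.2% of the variance, separated the groups, the high libraries lying at 14.9, 17.3 and 16.6 and the low libraries at -2.30, -17.3 and -29.1. Spearman correlations across genes were between 0.950 and 0.962 within the high group and between 0.915 and 0.940 within the low group, and no library repeated another. Across genes, low library 1 correlated slightly more with high library 1 (0.942) than with either of the low libraries. The biological coefficient of variation was 20.7%.

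The comparison of high with low intramuscular fat asks which muscle transcripts differ with fat content. SCD and 1 record of FASN, both genes of fatty acid synthesis, had the largest rises in the high group. SCD (ENSSSCG00000010554, chromosome 14, 120964210 to 120980992), which encodes the desaturase that makes monounsaturated fatty acids, was 16.8-fold higher, at 476 ± 147 CPM against 28.3 ± 9.41 CPM (SD, n = 3 per group). Its log2 fold change was 4.07 (SE 0.33, edgeR quasi-likelihood adjusted p = 0.00707). FASN, the fatty acid synthase, has 2 records that lie next to each other on chromosome 12, and both rose. The record ENSSSCG00000029944 (1023477 to 1034681) was 8.58-fold higher (153 ± 16.01 against 17.9 ± 3.19 CPM, adjusted p = 0.00149) and the record ENSSSCG00000023044 (1048559 to 1052166) was higher by 2.39 on the log2 scale (SE 0.30, adjusted p = 0.0446). ACACA, whose acetyl-CoA carboxylase supplies malonyl-CoA to that synthase, rose by 1.66 (SE 0.14, adjusted p = 0.00707; chromosome 12, 40200509 to 40367985).

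PLIN1 and 1 record of THRSP rose as well, as did 4 genes on none of the fat cell lists. PLIN1, which coats the lipid droplet of adipocytes, was higher by 2.75 (SE 0.32, adjusted p = 0.0404), at 42.6 ± 16.5 against 6.33 ± 1.65 CPM (chromosome 7, 60126614 to 60139897). THRSP, a thyroid hormone responsive regulator of lipogenesis, rose by 2.94 on its record ENSSSCG00000024447 (SE 0.35, adjusted p = 0.0437; chromosome 9, 13814634 to 13815671), while a second record of the same name stood at 1.05 (SE 0.21, adjusted p = 0.102). The mitochondrial carbonic anhydrase CA5B rose by 2.23 (SE 0.24, adjusted p = 0.0270; chromosome X, 13188041 to 13224941). The sorting receptor SORL1 rose by 2.21 (SE 0.19, adjusted p = 0.00707; chromosome 9, 53830781 to 53907681). The last 2 raised genes were PTPRS, a receptor tyrosine phosphatase (1.26, SE 0.16, adjusted p = 0.0499; chromosome 2, 74357680 to 74418111), and NOTCH2, a receptor of cell-to-cell signalling (1.18, SE 0.14, adjusted p = 0.0437; chromosome 4, 110927013 to 110985928).

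NCAPD3, a subunit of the condensin II complex that compacts chromosomes, was the 1 gene that fell past the threshold (chromosome 9, 67389926 to 67429731). It was 8.85-fold lower in the high group, at 7.88 ± 1.45 against 69.7 ± 19.4 CPM, a log2 fold change of -3.15 (SE 0.25, adjusted p = 0.00707). The 6 other listed records within 1 Mb of it had log2 fold changes between 0.10 and 0.38, with no adjusted p below 0.428. The next lower genes with a symbol did not pass. ACAD10 had -1.09 (SE 0.16, adjusted p = 0.0675) and ARMC6 -1.03 (SE 0.15, adjusted p = 0.0675). STARD7, a carrier of phosphatidylcholine to mitochondria, had -0.82 (SE 0.13, adjusted p = 0.0714). CEBPB, a transcription factor of early adipogenesis, had -0.75 on its record ENSSSCG00000024816 (SE 0.13, adjusted p = 0.0910). ENSSSCG00000023902, which has no symbol, did not pass either (quasi-likelihood adjusted p = 0.0675). Its log2 fold change by the authors' deposited values was -1.19.

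**Figure D1:**
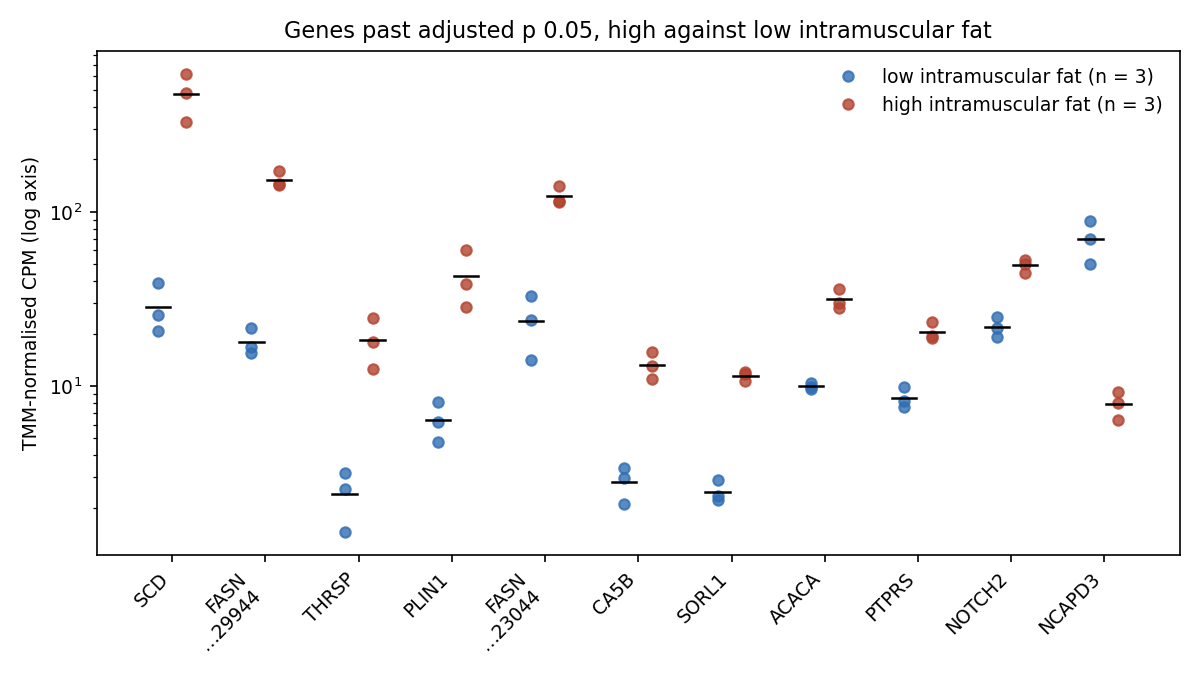
TMM-normalised CPM on a log axis for the 11 gene records past an adjusted p of 0.05, with 1 point per library (3 low in blue, 3 high in red) and a line at each group mean. In each record the groups do not overlap: SCD averages 476 CPM in the high and 28.3 CPM in the low group, and NCAPD3 averages 7.88 and 69.7 CPM.

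In all, 11 of 7661 gene records passed the threshold, 10 higher and 1 lower in the high group, and 1431 had an unadjusted p under 0.05 (787 higher, 644 lower). The groups did not overlap in 2054 genes, 26.8% of the table, where chance gives 10% per gene. Genes vary together across libraries, and the share in other groupings was not computed, so the excess is not a test. The choice of test moved the count: DESeq2 called 518 genes (377 higher, 141 lower) and edgeR's exact test 316 (249 higher, 67 lower), with all 11 among both. In the simulated data 17.0% of the calls of the exact test and 18.1% of those of DESeq2 were false. The count fell to 1 (FASN, ENSSSCG00000029944) without low library 2, to 2 without high library 2 and to 6 without high library 1, was 7 without high library 3 and 16 without low library 3, and rose to 30 without low library 1.

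Of the genes named in any case, CD36, a fatty acid translocase, stood at 0.54 (SE 0.19, adjusted p = 0.217) and LIPE, the hormone-sensitive lipase, at 1.15 (SE 0.45, adjusted p = 0.237), or at 0.53 without high library 3. FABP3, the fatty acid binding protein of muscle, had -0.61 and -0.63 on its 2 records (adjusted p = 0.230 and 0.281). The fibre type genes MYH7 (slow) and MYH4 (fast) had -0.21 (SE 0.36) and 0.22 (SE 0.21), and PPARGC1A, listed as PPARGC1, 0.02 (SE 0.46), none past the threshold. Reads can be shared among the myosin heavy chain genes.

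The list of lipogenesis and triglyceride synthesis had 11 measured records, of which 7 were higher in the high group without overlap of the groups and 4 were lower. 4 records passed over all genes and 7 when adjusted over the list alone, with a list median of 1.32 (camera adjusted p = 2.45e-06; adjusted p = 0.136 with an estimated correlation, unadjusted p = 0.00568). Beside SCD, FASN and ACACA, the elongase ELOVL5 had 1.45 (SE 0.19, adjusted p = 0.0551), the citrate lyase ACLY 1.32 (SE 0.23, adjusted p = 0.0910) and the NADPH-forming malic enzyme ME1 0.89 (SE 0.19, adjusted p = 0.108). AGPAT2, an enzyme of glycerolipid assembly, stood at -1.10 (SE 0.48, adjusted p = 0.273), and at -0.28 without low library 3. Among 8 adipocyte marker records, 6 were higher and 2 lower, with a median of 1.11 (camera adjusted p = 0.00129; adjusted p = 0.603 with an estimated correlation); 2 passed over all genes, and 5 higher and 1 lower when adjusted over the list alone. CIDEC, listed as CIDE-C, had 2.38 (SE 0.55, adjusted p = 0.114; 3.13 without low library 3) and CIDEA 1.17 (SE 0.26, adjusted p = 0.112), both proteins of lipid droplets, whereas the glycerol channel AQP7 had -0.66 (SE 0.24, adjusted p = 0.2203).

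Connective tissue genes formed the next group. All 26 records of the fibroblast and extracellular matrix list were higher in the high group, with a median of 0.76. COL1A1, COL1A2 and COL5A1 had more than 1 of these records each, and such records can share reads. The camera adjusted p of the list was 2.68e-10, or 0.629 with an estimated correlation. None of the records passed the threshold over all genes, and 15 did when adjusted over the list alone. Elastin (ELN) had 0.96 (SE 0.17, adjusted p = 0.0910), COL14A1 1.48 (SE 0.30, adjusted p = 0.104), COL5A2 0.999 (SE 0.23, adjusted p = 0.114) and PDGFRA, a receptor of fibroblasts and of fat cell progenitors, 1.43 (SE 0.36, adjusted p = 0.131). The 12 basement membrane records, more than 1 of them of COL15A1, were also all higher (median 0.49). Their camera adjusted p was 9.38e-06, or 0.603 with an estimated correlation. Over all genes 0 of these records passed the threshold, and 7 did when adjusted over the list alone. LAMA4 had 0.59 (SE 0.12, adjusted p = 0.0994), HSPG2 0.83 (SE 0.18, adjusted p = 0.110), the COL15A1 record ENSSSCG00000005380 0.67 (SE 0.20) and LAMC1 0.73 (SE 0.22).

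Nuclear genes of oxidative phosphorylation were lower in the high group in 27 of 28 records, by little: the median was -0.18 (camera adjusted p = 9.12e-04; adjusted p = 0.702 with an estimated correlation), and 0 passed over all genes or adjusted over the list alone. SDHB had -0.46 (SE 0.14), NDUFV1 -0.35 (SE 0.13), NDUFS3 -0.39 (SE 0.15) and COX4I1 -0.32 (SE 0.13). Fold changes in this comparison rose with the genomic span of the gene, with Spearman's rho of 0.407 across 7661 genes, which are not independent replicates. On mean log2 CPM the real grouping gave 0.403 and the other 9 groupings of the libraries, 3 against 3, between -0.358 and 0.337. The sign in those 9 is arbitrary, because the side holding low library 1 was always taken as low. In size, -0.358 and 0.337 are near the real value. The bin of the longest genes (median span 278 kb) had a median of 0.27 and that of the shortest (0.0985 kb) -0.16. In single libraries the rho of span with the deviation from the mean of all libraries was 0.230, 0.355 and 0.240 for high libraries 1 to 3 and -0.0644, -0.144 and -0.417 for low libraries 1 to 3. With that trend removed in each library, an alternative chosen after seeing the data, 9 genes passed, all among the 11; NOTCH2 (1.04, adjusted p = 0.0666) and PTPRS (1.14, adjusted p = 0.0807) no longer did. The matrix, basement membrane, lipogenesis and adipocyte lists stayed past the threshold (adjusted p = 5.20e-11, 3.65e-04, 1.05e-05 and 2.04e-04), as did the circadian and interferon lists described next (adjusted p = 0.00613 and 0.0338). The oxidative phosphorylation list did not stay past it (adjusted p = 0.0529).

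**Figure D2:**
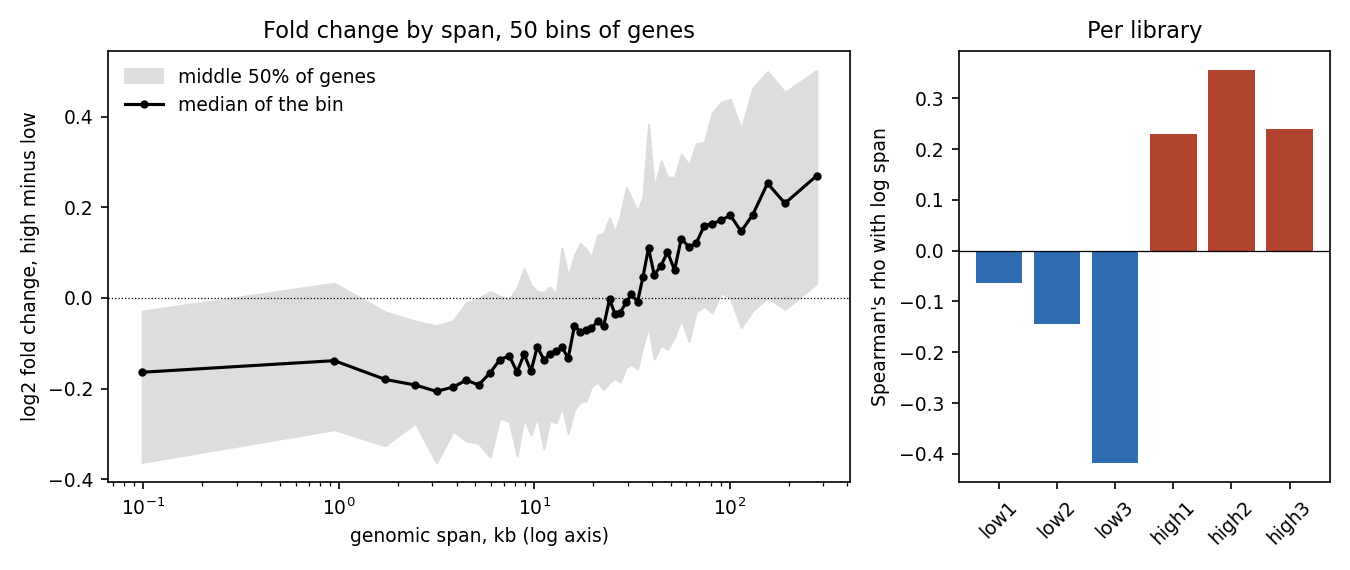
Left, median log2 fold change (high minus low) of genes in 50 bins of genomic span in kb on a log axis, with the middle 50% of genes shaded. Right, Spearman's rho across genes between log span and each library's deviation from the mean of the 6 libraries, positive in the 3 high libraries (0.230 to 0.355) and negative in the 3 low libraries (-0.417 to -0.0644).

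The circadian clock list was higher in 10 of 12 records (median 0.40, camera adjusted p = 0.00332; adjusted p = 0.603 with an estimated correlation), with 0 past the threshold over all genes and 4 when adjusted over the list alone. The nuclear receptors NR1D2 and RORA had 0.65 (SE 0.15, adjusted p = 0.113) and 0.995 (SE 0.28, adjusted p = 0.152), CIART, listed as C1ORF51, had 1.19 (SE 0.29, adjusted p = 0.123) and PER3 0.64 (SE 0.18, adjusted p = 0.151). All 8 interferon response records were lower (median -0.83, camera adjusted p = 0.0428; adjusted p = 0.702 with an estimated correlation), with 0 past the threshold over all genes or adjusted over the list alone. The low libraries differed here: IFI44 was at 50.5 CPM in low library 3 against 12.2 and 13.9 CPM in low libraries 1 and 2 and 9.52 ± 2.66 CPM in the high group (log2 fold change -1.42, SE 0.54). DDX58 (-1.22, SE 0.49), IFIT1 (-1.02, SE 0.47) and PSMB8 on its record ENSSSCG00000026951 (-0.81, SE 0.44) did not pass either. Without low library 3, IFI44 had -0.45, DDX58 -0.30 and IFIT1 -0.25, and without low library 2 PSMB8 had -0.24. The list lost its call without low library 2 (adjusted p = 0.0716), low library 3 (adjusted p = 0.0795) or high library 1 (adjusted p = 0.163). No list held its call with an estimated correlation after adjustment.

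**Figure D3:**
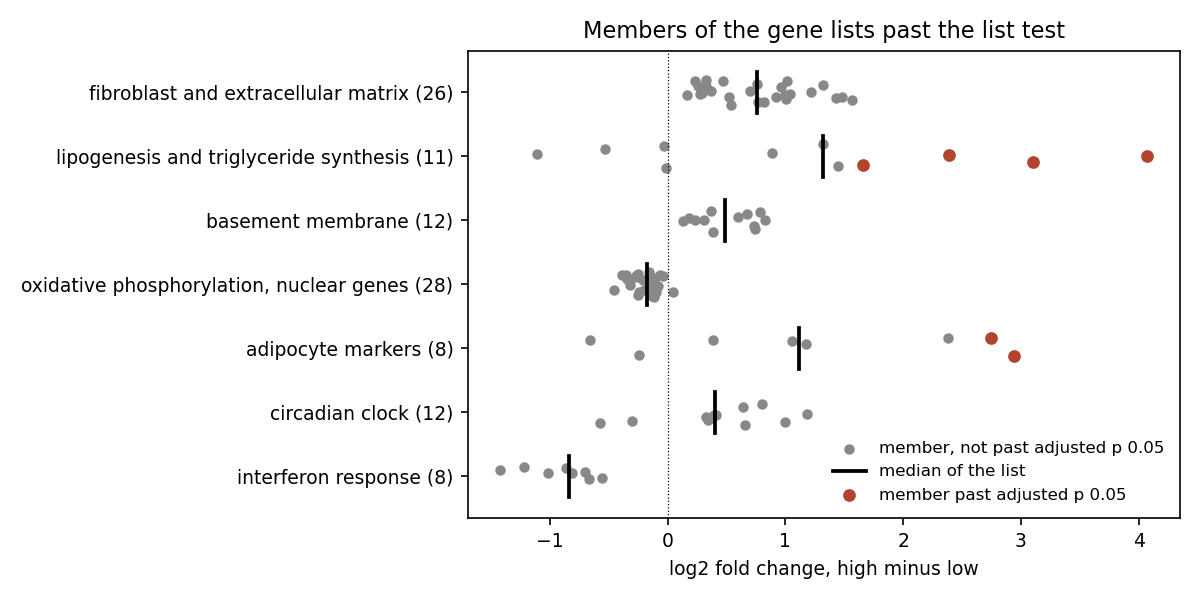
Log2 fold change, high minus low, of each measured member of the 7 lists past the list test, with the number of records in brackets, a line at the list median and members past an adjusted p of 0.05 in red. Matrix and basement membrane members all lie above 0, interferon response members all below, and the called members belong to the lipogenesis and adipocyte lists.

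The other 17 lists tested did not pass. Glycolysis and glycogen (median 0.09, adjusted p = 0.0719) and immediate early genes (0.32, adjusted p = 0.0719) came nearest, followed by fatty acid oxidation (-0.10, 19 of 26 lower, adjusted p = 0.0974), ribosomal proteins (-0.16, adjusted p = 0.0974) and insulin signalling (0.29, adjusted p = 0.101). With the span trend removed, glycolysis (adjusted p = 0.0172), immediate early genes (adjusted p = 0.00613) and fatty acid oxidation (adjusted p = 0.0478) passed. Medians were 0.05 for smooth muscle and pericyte markers, 0.30 for satellite cell genes, -0.21 for mitochondrially encoded genes, -0.28 for heat shock genes, -0.29 for slow fibre genes (9 of 10 lower), 0.09 for fast fibre genes, -0.15 for lipolysis and lipid droplet genes, 0.17 for atrophy genes and -0.04 for fatty acid uptake, with adjusted p between 0.167 and 0.447. Macrophage markers (median -0.10, mean 0.13), endothelial markers (-0.01, mean 0.08) and adipogenic transcription factors (0.21, mean -0.09) had medians whose sign differed from that of the mean and of the test (adjusted p = 0.359, 0.491 and 0.888). Of the 17 lists, adjusted over the list alone, glycolysis held 2 higher genes, immediate early genes 2 higher and 1 lower, satellite cell genes 1 higher and 1 lower, smooth muscle 1 higher, fatty acid oxidation 1 lower and adipogenic factors 2 lower records. Erythrocyte (median -0.18, 2 records), Schwann cell (-0.11, 2 records), lymphocyte (0.27, 1 record) and sex-linked (-0.37, 1 record) markers were too few to test, and neutrophil markers are not analysed here. The lymphocyte record is listed as CD8B. Its mean log2 CPM was 8.99 in the high and 8.73 in the low group, against 4.97 and 4.73 for the macrophage markers. Whether its reads came from lymphocytes was not tested. The sex-linked record is listed as ZFY but lies on chromosome X.

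The authors' deposited list holds 134 genes, 106 higher and 28 lower in the high group by the authors' deposited fold changes. All 134 had the same sign in the quasi-likelihood fit and an unadjusted p under 0.05, and 11 of them passed its threshold; 125 passed in DESeq2. The list was drawn from these same libraries and is not independent evidence. In the authors' deposited table the largest rises were those of SCD, FASN, THRSP and PLIN1, followed by PRKG1, the cyclic GMP dependent kinase (chromosome 14, 106253479 to 106707670), which stood at 127 ± 61.3 against 19.98 ± 3.39 CPM here (2.67, SE 0.36, adjusted p = 0.0552). After NCAPD3 the largest falls were those of ENSSSCG00000021903, the interferon-induced ISG12(A) and GBP6, and ENSSSCG00000014565. In the fit used here these 4 had -2.26 (SE 0.73), -2.13 (SE 0.87), -2.11 (SE 0.73) and -1.96 (SE 0.50), and none passed (adjusted p between 0.133 and 0.251). Without low library 3, ISG12(A) had -0.14, ENSSSCG00000021903 -1.06 and ENSSSCG00000014565 -1.14, and without low library 2 GBP6 had -1.27.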

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

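The exact test, the older quasi-likelihood method, library sizes from the listed genes, removal of the mitochondrial genes or of the span trend, and high libraries 1 and 2 left out together were chosen after seeing the data; the lone high library was then assumed to vary like the others. The 11 calls became 518 in DESeq2 (377 higher, 141 lower), 316 in the exact test (249, 67), 2 with the replicate block (1 higher), 82 at a threshold of 0.1 (69, 13) and 0 without high libraries 1 and 2 (0, 0; 596 at an unadjusted p under 0.05). With each library left out they numbered 1 to 30 (higher 1 to 22, lower 0 to 8): 30 without low library 1, 1 without low 2, 16 without low 3, and 6, 2 and 7 without high 1, 2 and 3. Of the 134 deposited genes, 125 passed in DESeq2, 2 with the block, and 1 to 28 with each library left out (28 without low 1, 1 without low 2). All 134 passed in the exact test, which was fixed in advance because that test gave the authors' fold changes and p-values. Other alternatives gave 8 to 16 calls. FASN (ENSSSCG00000029944) passed in every alternative chosen before the data were examined (log2 fold change 3.01 to 3.26); all 11 kept their direction. Of the 24 lists, 7 passed, against 0 with an estimated correlation, 7 to 11 with each library left out (11 without low 1) and 6 to 9 in the other alternatives; these counts include lists outside the 7. Of the 7, interferon lost its call without low 2, low 3 or high 1. With an estimated correlation the adjusted p was 0.603 (adipocyte, basement membrane, circadian), 0.629 (matrix), 0.702 (interferon, oxidative phosphorylation) and 0.136 (lipogenesis), and on ranks 0.0519 (adipocyte). With the block, glycolysis (0.0342) and insulin (0.0416) passed. With the span trend removed, fatty acid oxidation (0.0478), glycolysis (0.0172) and immediate early genes (0.00613) passed and oxidative phosphorylation (0.0529) did not. Without high libraries 1 and 2, heat shock (0.0428), insulin (0.0374) and atrophy (0.0181) passed and interferon (0.169) did not. Lists that changed direction were adipogenic factors (ranks 0.763; both high libraries out 0.618; each library out 0.574 to 0.967, reversed without low 2, high 1 and high 2), fast fibre (both out 0.490; each out 0.206 to 0.859, reversed without low 2 and high 1), mitochondrially encoded (both out 0.0666; each out 0.00159 to 0.792, reversed without low 1 at 0.598) and ribosomal (span trend 0.607; each out 0.00177 to 0.206, reversed without low 3 at 0.206). The lowest values of the last 2 kept the direction. Reversed without the 1 library named were endothelial (0.190 to 0.982; without low 3 0.579), heat shock (0.0123 to 0.740; without low 3 0.0795), macrophage (0.0714 to 0.582; without low 1 0.360), atrophy (0.238 to 0.870; without high 3 0.870) and slow fibre (9.13e-04 to 0.898; without low 2 0.898). The list of interferon response reached 0.00177 to 0.163 with each library out, fatty acid oxidation 0.0317 to 0.343, glycolysis 0.00733 to 0.371, immediate early genes 1.52e-04 to 0.544 and insulin 0.0383 to 0.432. PPARGC1 had -0.066 in limma-voom, -0.10 with the block, -1.07 with both high libraries out, -0.037 without the span trend and -0.52 to 0.40 with each library out; MYH7 had 0.021 with both out and -0.52 to 0.11 with each out. The no-filter and mean CPM settings removed no gene and say nothing on stability. The cause was not tested for any of these changes. Where a library was left out, having fewer libraries was not separated from which library was missing.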

Other observations

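Several tests were chosen only after the results were seen. They were those of the lipogenic genes, of the matrix genes against endothelial markers and of the oxidative phosphorylation genes against the span trend. Those of the mitochondrial tRNAs and of the X-linked genes were too, as were the splits for gene counts in both edgeR tests. The genes of the next paragraph were picked after their values were seen.

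Some single genes had an adjusted p between 0.05 and 0.1 in the edgeR quasi-likelihood test; none passed, and no common function of them was tested. RETSAT, a retinol saturase, had a log2 fold change of 1.81 (adjusted p = 0.0727), the pyruvate carboxylase PC 0.94 (adjusted p = 0.0946), IDH1 0.91 (adjusted p = 0.0761) and the amine oxidase AOC3 0.93 (adjusted p = 0.0940). AGT, the angiotensin precursor, had 1.14 (adjusted p = 0.0910), and ASPN, a small matrix proteoglycan whose locus overlaps CENPP, 1.06 (adjusted p = 0.0525). Lower were NMRK2 at -0.98 (adjusted p = 0.0910) and MRPL12 at -0.81 (adjusted p = 0.0910).

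The 6 libraries can be split 3 against 3 in 10 ways, too few for a share under 0.05. The real split gave 11 genes and the highest other 3, so 1 of 10 splits gave as many. In the exact test the real split gave 316 and the highest other 24, again 1 of 10. For the lists the real split gave 7 and the highest other 12, and 9 of 10 splits gave at least as many. A camera p as small as that of the real split came from 3 of 10 splits for the matrix list (1.12e-11, smallest other 1.89e-15), 4 for oxidative phosphorylation, 3 for interferon response and 2 for the circadian list. For lipogenesis, adipocyte markers and basement membrane it came from 1, the real split.

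Some lipogenic genes rose in the high group beside some fat cell genes. A larger share of fat cell RNA alone would raise all members of both lists if fat cells were their main source. Their source was not tested. The mean log2 CPM over the 11 lipogenesis records was higher by 1.23 and that over the 8 adipocyte marker records by 1.21, a difference of 0.017 (SE 0.23). The 8 records lack ADIPOQ, LEP, FABP4 and other unmatched markers of that list. They include the records of THRSP, itself a regulator of lipogenesis, so the lists are not fully separate measures. Members of both lists went both ways, PLIN1 at 2.75 and CIDEC at 2.38 (3.13 without low library 3) but PLIN4 at 0.38, CFD at -0.24, AQP7 at -0.66 without overlap of the groups, and AGPAT2 at -1.10 (-0.28 without low library 3), so this difference decides nothing. A larger share of fat cells and a change of expression within cells cannot be told apart here, and other differences between the animals were not tested.

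Matrix genes were higher in the high group. The trend with span accounted for little of this: after centring on it the list median was 0.69 against 0.76 before. Of random lists of the same size 95% lay between -0.11 and 0.12. Their genes were drawn independently, whereas matrix genes vary together (estimated correlation 0.606), so that range is too narrow to test the list. For oxidative phosphorylation the median went from -0.18 to -0.070, inside the range of random lists (-0.11 to 0.12), so the trend with span may account for those lower values. A lower share of muscle fibre RNA would raise markers of the other cell types alike. The matrix minus endothelial score was higher in the high group by 0.68 (SE 0.36), but low library 3 (1.10) lay among the high libraries (1.19, 1.40 and 0.88), and the alternatives cannot be told apart with libraries this variable.

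Some mitochondrial tRNA genes were far lower in high libraries 1 and 2. Of 20 mitochondrial genes under 100 bases, 9 were lower in these 2 libraries than in each other library and 3 at least 5 times lower. ENSSSCG00000018074 had 0.700 and 0.266 CPM, against 27.9, 13.8 and 44.1 CPM in the low libraries and 42.9 CPM in high library 3. Others of the 9 were lower by little, such as ENSSSCG00000018076 (1353 and 1472 CPM, against 1511 CPM in high library 3). The order alone was not particular to short genes. Most protein-coding mitochondrial genes shared it, such as MT-CO3 (6746 and 6596 CPM, against 8647 to 13358 CPM in the others). MT-ND4L, NADH4 and MT-ND5 did not. For 99 nuclear genes under 150 bases, the median ratio to the low libraries was 0.857 in high library 1 and 0.911 in high library 2. It was 0.860 in high library 3. Whether their reads came from short RNA or from longer transcripts was not tested. These ratios therefore cannot decide on a loss of short RNA. Of 10 X-linked genes, 4 (EIF2S3, ZFX, KDM6A and TXLNG) were lower in high libraries 1 and 2 than in each of the others. Chance would give 6.67% per gene if the libraries were all equally alike. High libraries 1 and 2 were the most alike pair (Spearman correlation 0.962). The share over all genes was not computed, so the 4 genes are not a test. The record taken as ZFX is listed as ZFY but lies on chromosome X, and it is the sex-linked record given above. EIF2S3 had 63.0 and 63.5 CPM against 99.7 to 120 CPM in the others. A different number of X chromosomes cannot be told apart from other differences between the animals, since sex is not given in the sources used here. Mitochondrial sequence differences from the reference were not tested.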
